A study of Mus musculus with 4 samples.

How the data were processed

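RNA was measured in 4 libraries of primary mouse bone marrow mesenchymal stem cells (MSCs), 1 library for each combination of genotype label (wild type, WT, or Kdm4b knockout, KO) and medium (control or osteogenic induction for 4 days). Per the labels, polyadenylated RNA was purified on beads and made into libraries with a stranded kit. The deposited values were FPKM, fragments per kilobase of transcript, scaled to the number of mapped fragments, per the file headers. Per the submitters' processing notes, the authors used TopHat and Cufflinks with the mouse genome build mm9. The versions of both tools, the gene annotation, the use of the strand and any filters were not given in the sources used here.

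The values stood in 2 deposited tables, one with the control libraries and one with the induced libraries, each with 24346 entries. The libraries were assigned to the media by the column names alone, since the sheet of the control table carried the abbreviation for osteogenic induction in its name. In each of them, entries with a date in place of a gene symbol, 27 in number, were left out, which removed at most 0.169% of the summed FPKM of a library. The 24319 entries used had no repeated symbol, 103 of them named more than 1 gene, and 1293 were small RNA genes. A column of log2 ratios by the authors was checked and equalled log2(KO/WT) within 1e-06 for all 15522 numeric values of the control table and all 15269 of the induction table. It was not used further. How the tables were normalized to each other was not given in the sources used here, so comparisons of induction with control set values from separate tables side by side. The median-ratio factors of the 4 libraries lay between 0.984 and 1.02.

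No read counts were used, so the depth of the libraries and the counting error of a value are unknown. The smallest step of a low FPKM reflects the depth, and the most frequent ratio among genes with values above 0 and below 0.15 FPKM in both libraries gave the depth relative to the control library labelled WT, from 984 to 1372 genes. Small RNA genes and Rn45s together held 11.4% to 14.0% of the summed FPKM, and the 10 most abundant entries held 18.9% to 22.3%.

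The main comparisons were KO against WT in control medium and under induction, followed by induction against control within each genotype label. Each main comparison shares a library with each induction comparison, so their results are not independent of each other. With 1 library per group there were no replicates, so the comparisons within a medium or a genotype label have no test, p-value, standard error or check against the spread between replicates. An additive fit of genotype and medium over all 4 libraries, which leaves 1 residual degree of freedom and takes the genotype effect to be equal in both media, was not run. For each gene the log2 ratio of FPKM + 1 was computed, and genes with at least 1 FPKM in one of the libraries compared were counted as higher or lower at a log2 ratio of at least 1 in size, a 2-fold difference. Overlaps between comparisons are given beside the number that independent lists of the same sizes would share. For 28 gene lists, of which 603 of 611 genes were found, the median log2 ratio of the measured genes was set against 10000 random lists matched on the decile of mean log2(FPKM + 1), drawn with replacement. A list stood apart when its median lay among the lowest or the highest 2.5% of the random lists, and lists with fewer than 5 measured genes are given as values only. The lists covered H3K9 methylation, osteoblasts, adipocytes, Wnt and BMP targets, DLX and HOX genes, marrow stromal markers, cell cycle arrest, secreted factors of senescent cells, the cell cycle, fibrillar matrix, the interferon response, and chondrocyte, contractile, macrophage, osteoclast, other hematopoietic, endothelial and skeletal muscle genes. They further covered ribosomal proteins, the respiratory chain, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, immediate early genes, NRF2 targets, the glucocorticoid response and the sex of the animal. The comparisons, the lists, the naming rule and the first set of alternatives were fixed before the data were examined. A further 4 lists were composed after values had been seen and are given only in the closing section.

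The naming rule took Kdm4b, the 12 genes with the largest log2 ratio each way in each main comparison, the 6 largest each way in each induction comparison and the 8 largest each way among genes past the size rule in both media. These needed at least 5 FPKM in the higher library, and predicted genes, microRNA genes and small RNA genes recognised by their symbols were left out. From each list it took up to 4 genes past the size rule, or the 2 with the largest ratios where none passed. Some genes that the rule took are not named in the text. Alpl, Bglap2, Cd68, Cdkn1a, Col1a1, Col1a2, Kdm5d, Lyz2, Mki67, Ptprc, Runx2 and Spp1 are members of the lists that fell outside this rule and were chosen after their values were seen, and genes named in one comparison are also given in others.

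Alternatives were pseudocounts of 0.1 and 5, no expression filter and a minimum of 5 FPKM, median-ratio scaling, a size rule of 1.5, and, for the lists, 20 expression bins and the mean in place of the median. Leaving out small RNA genes, leaving out genes listed at 0, removing the trend of the ratio with transcript length or with GC content, and using the control library labelled WT as the reference under induction were added after the data had been seen. Trends were running medians over 40 bins. Length and GC content were medians over the protein-coding transcripts of each symbol in GENCODE mouse release M21, which belongs to a later genome build than mm9. It was used for these properties alone and covered 96.3% of the genes. No coordinates are given. The level of Kdm4b was set against the 1000 genes closest to it in mean level.

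The procedure was tested on simulated data in the format of the deposited tables. All 200 genes changed by a log2 ratio of 2 were counted in each medium, and 0 unchanged genes were counted. The changed genes were drawn among those with a mean of at least 5 FPKM, so recovery of genes with lower values was not covered. Of 200 unchanged lists, 5% and 7% stood apart, and all lists shifted by 0.5 did. The simulated noise was independent between genes, with no trend with transcript length or GC content. It was small beside the real ratios, whose standard deviation without small RNA genes was 0.41 in control medium and 0.67 under induction. The simulation therefore checked the procedure and gives no error rate for the deposited values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.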

Results

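Polyadenylated RNA was sequenced from primary mouse bone marrow mesenchymal stem cells (MSCs), the adherent stromal cells of the marrow that can give rise to bone, fat and cartilage cells. Cells labelled wild type (WT) and cells labelled knockout (KO) for Kdm4b, a histone demethylase acting on methylated lysine residues of histone H3, were cultured for 4 days in control medium or under osteogenic induction, a treatment that drives such cells towards osteoblasts. Each of the 4 groups held 1 library, so there were no replicates, and the values below come without p-values, standard errors or a spread between cultures. Expression was given as FPKM, fragments per kilobase of transcript, scaled to the number of mapped fragments. Differences are stated as log2 ratios of FPKM + 1, a scale that understates the difference of genes with low values. A gene was counted as higher or lower when this ratio was at least 1 in size and the gene had at least 1 FPKM in one of the libraries compared. A gene list was said to stand apart when the median of its genes lay among the lowest or the highest 2.5% of 10000 random lists matched on expression. Such a percentile describes these libraries and is not a p-value, since genes of one list vary together. The number of genes with at least 1 FPKM was 11542 in the control library labelled WT, 11482 in the control library labelled KO, 11450 in the induced library labelled WT and 11392 in the induced library labelled KO. Read totals were not part of the values used here. From the steps between low values, the depth relative to the control library labelled WT was estimated at 0.88 for the control library labelled KO, 0.84 for the induced library labelled WT and 1.11 for the induced library labelled KO.

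Kdm4b, the targeted gene, was measured at 4.60 FPKM in the control library labelled WT and 4.30 FPKM in the control library labelled KO. Under induction it was at 5.83 FPKM in the library labelled WT and 4.26 FPKM in the library labelled KO. The log2 ratios of KO to WT were -0.08 in control medium and -0.38 under induction, at the percentiles 34.9 and 31.9 of the 1000 genes closest to Kdm4b in level. A gene-level value does not resolve single exons, and the Kdm4b level alone did not tell the libraries labelled KO from those labelled WT. Every direction below is therefore between libraries as labelled. Fkbp5, a glucocorticoid-induced co-chaperone, was at 4.10 and 3.94 FPKM in the control libraries labelled WT and KO and at 118 and 79.3 FPKM in the induced ones. The sex-linked genes set the induced library labelled WT apart. Xist, the RNA that silences one X chromosome in female cells, was at 24.0, 30.5 and 21.6 FPKM in the control WT, control KO and induced KO libraries and at 0.0621 FPKM in the induced library labelled WT. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at 28.7, 39.4, 8.20 and 4.79 FPKM in the induced library labelled WT. In the other libraries Ddx3y was at or below 0.0208 FPKM and the other Y-linked genes were listed at 0. Markers of macrophages, the phagocytic cells of the myeloid lineage, were abundant in every library. Lyz2, which encodes lysozyme, was at 7937, 6915, 6763 and 6734 FPKM in the control WT, control KO, induced WT and induced KO libraries, and the macrophage marker Cd68 was at 1201, 1034, 490.0 and 845 FPKM. Among the 6 pairs of libraries, the 3 without the induced library labelled WT differed by the size rule in 284 to 334 genes, and the 3 with it differed in 1190 to 1834 genes.

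**Figure D1:**
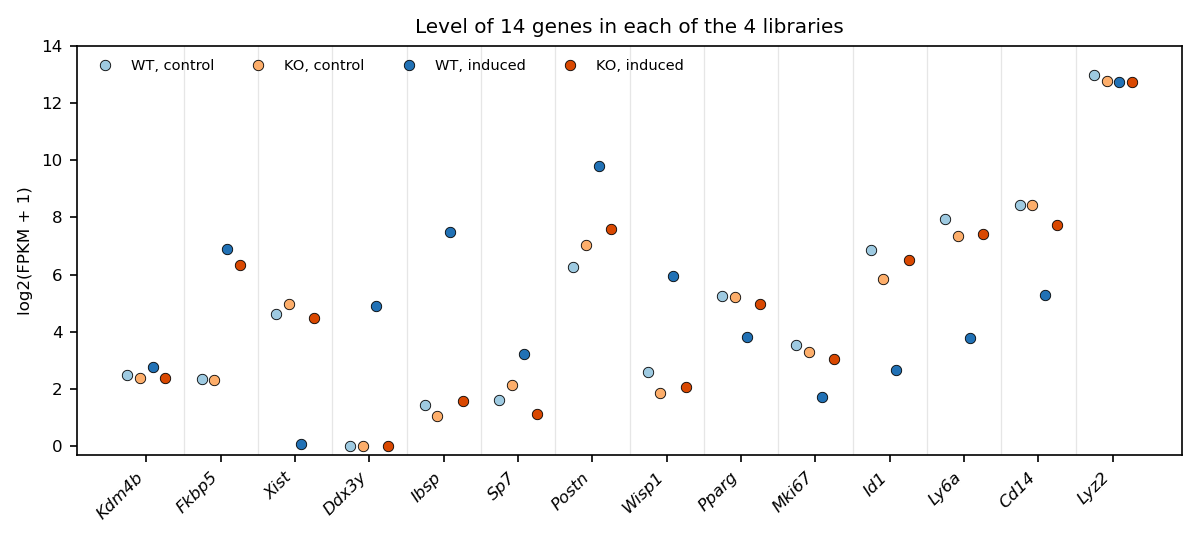
Level of 14 genes in each of the 4 libraries, as log2(FPKM + 1), with 1 point per library. Kdm4b lay between 4.26 and 5.83 FPKM in all 4 libraries, Fkbp5 was high in both induced libraries, and Xist, Ddx3y, Ibsp and Id1 set the induced library labelled WT apart from the other 3.

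The first comparison asked how cells labelled Kdm4b KO differed from those labelled WT in control medium. In the library labelled KO the median of the fibrillar matrix list lay above all random lists and those of the interferon and ribosomal protein lists below all of them, while 3 of 22, 3 of 21 and 0 of 36 of their genes passed the size rule. Dcn, the small proteoglycan decorin that binds collagen fibrils, was at 17.5 FPKM in the library labelled KO and 1.72 FPKM in the library labelled WT, a log2 ratio of 2.77. Col3a1, which encodes type III collagen, was at 158 and 59.0 FPKM (log2 ratio 1.41). The interferon-stimulated gene Isg15 was at 7.09 FPKM in the library labelled KO and 15.9 FPKM in the library labelled WT (log2 ratio -1.06). By the size rule, 284 of 11845 genes differed, 110 of them higher and 174 lower. Small RNA genes, which are poorly measured in such libraries, made up a large part, and without them 176 genes differed, 78 higher and 98 lower.

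Of the named genes that were higher in the control library labelled KO, Dcn was followed by Clmp (log2 ratio 1.99), which encodes a cell adhesion molecule, and Pla1a (1.98), a phospholipase. Cacng7 had a ratio of 1.93 and Col2a1, the main collagen of cartilage, of 1.90. The lower genes were led by Mrap, an accessory protein of the melanocortin receptor, at 2.78 FPKM against 14.1 FPKM, and by Aldh1a1 (-1.99), an enzyme of retinoic acid synthesis. They went on with Ugt1a6b (-1.90), Cadm4 (-1.73), Ccl7 (-1.73), a chemokine that attracts monocytes, Pmp2 (-1.68), Sfn (-1.56), Apod (-1.47), Trnp1 (-1.47), Gpx3 (-1.45), the secreted glutathione peroxidase, and Cryab (-1.45), a small heat shock protein. Some large ratios were uncertain because the genes share sequence with others. Rn45s, the ribosomal RNA precursor, was listed at 0 in the control library labelled WT and was at 13586, 12553 and 15014 FPKM in the control KO, induced WT and induced KO libraries. Erdr1 (log2 ratio 4.34), Atp6v0c (3.08) and the joint entry Amd1,Amd2 (2.99) have near-identical copies or repeats. The entries Rps27,Rps27rt (1.70) and Rps27rt (-1.57) had opposite ratios, and their sum was 2490 FPKM in the library labelled WT and 1523 FPKM in the library labelled KO. Ugt1a6b shares exons with other genes of its cluster.

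Among the gene lists, 7 of 26 stood apart in control medium. Lists of independently drawn genes would give 1.3, which is no chance level for lists whose genes vary together. The fibrillar matrix list had a median of 0.35, above all 10000 random lists, with 3 of 22 genes higher, namely Dcn, Col3a1 and Lum (1.11), and 0 lower. The marrow stromal and skeletal stem cell list had a median of 0.36, also above all random lists. Its member Prrx1 (1.01), a mesenchymal transcription factor, was higher, Mcam (-1.20) and Nes (-1.15), both found in perivascular stromal cells, were lower, and 16 of 19 genes were within the rule. Cholesterol synthesis genes had a median of 0.37 (percentile 99.99), with Stard4 (1.12), a sterol transporter, past the rule. The type I interferon list had a median of -0.58, below all random lists, with 3 of 21 genes lower, namely Rtp4 (-1.16), Isg15 and Usp18 (-1.03). The DLX and HOX homeobox list had a median of -0.38 (percentile 0.02). Its lower genes were Hoxb2 (-1.18) and Hoxb6, which was at 1.45 FPKM in the library labelled WT and listed at 0 in the library labelled KO. This call was lost among genes with at least 5 FPKM, where the percentile was 19.4. All 36 cytosolic ribosomal protein genes had ratios below 0, with a median of -0.62 that lay below all random lists and with 0 genes past the rule. Rpl38 had a ratio of -0.92 and Rps15 of -0.85. The respiratory chain list had a median of -0.40 (percentile 0.975), with Cox4i1 at -0.72 and Ndufa2 at -0.68. The log2 ratios also followed trends across all genes. The log2 ratio ran with transcript length (Spearman rho 0.44 over 11410 genes) and ran against GC content (rho -0.41), with genes that are not independent of each other. With the length trend removed, the ribosomal list stayed below all random lists with a median of -0.41, and the respiratory chain list lay at the percentile 19.8.

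The lists for bone and fat did not stand apart in control medium. Of 18 osteoblast and bone matrix genes, 0 passed the rule and the median was 0.07 (percentile 78.9), with the largest ratios for Msx2 (-0.92), a homeobox factor of early osteoblasts, and Tnfrsf11b (0.69), the decoy receptor osteoprotegerin. Of 20 adipocyte genes, 0 passed the rule and the median was -0.10 (percentile 36.7). Pparg, the nuclear receptor that directs fat cell formation, was at 36.7 FPKM in the library labelled KO and 37.3 FPKM in the library labelled WT. Medians within the random range were also found for the Wnt target (-0.04), BMP target (-0.19), cell cycle arrest (-0.09), senescent cell secretion (-0.08), cell cycle (-0.13), H3K9 methylation (0.08), chondrocyte (0.09), contractile (-0.18), osteoclast (0.24), other hematopoietic (-0.43), endothelial (-0.11), glycolysis (-0.25), unfolded protein (-0.11), immediate early (0.06), NRF2 (-0.06) and glucocorticoid (-0.04) lists. Of these, the Wnt list stood apart among genes with at least 5 FPKM (median -0.38, percentile 1.18), the cell cycle list with the GC trend removed (percentile 0.42) and the other hematopoietic list with a pseudocount of 5 (percentile 2.25). Within these lists some genes passed the rule. The BMP target Id1, an inhibitor of helix-loop-helix factors, was at 56.5 FPKM against 114 FPKM in the library labelled WT. The chemokine Ccl2 had -1.16, the growth factor Hgf 1.43, the survival and mitosis gene Birc5 -1.03, the cartilage matrix gene Comp -1.25, the pericyte gene Rgs5 1.04, the osteoclast phosphatase Acp5 -1.04 and the stress factor Ddit3 -1.06. The macrophage list had a median of -0.08 at the percentile 87.0, its matched random lists having a median of -0.19, and Itgam (1.08) was its only member past the rule. The skeletal muscle list had 1 measured gene, Acta1 (-1.05), and of the sex list only Xist (0.33) reached 1 FPKM.

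The second comparison asked the same question under osteogenic induction, where 12 of 19 osteoblast genes and 7 of 22 fibrillar matrix genes were lower in the library labelled KO than in the library labelled WT. Ibsp, the bone sialoprotein of mineralising matrix, was at 1.98 FPKM in the library labelled KO and 176.8 FPKM in the library labelled WT, a log2 ratio of -5.90. Sp7, the transcription factor osterix that osteoblasts need, was at 1.18 and 8.46 FPKM (log2 ratio -2.12), and Alpl, the alkaline phosphatase of bone, at 4.58 and 15.7 FPKM (-1.58). Of the cell cycle genes, 18 of 32 were higher in the library labelled KO, with Mki67, a marker of dividing cells, at 7.22 and 2.30 FPKM (1.32), and so was Pparg, at 30.5 and 13.2 FPKM (1.15). By the size rule, 1273 of 11936 genes differed, 629 of them higher and 644 lower. The sex-linked genes differed between the same libraries, so genotype was not separated from the sex of the animal in any value of this comparison. When the control library labelled WT took the place of the induced one, a choice made after the data had been seen, 334 genes differed. Those libraries differ in medium as well as in genotype label.

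The named genes that were higher in the induced library labelled KO included Plac8 (log2 ratio 5.12), Mfap5 (4.46), a microfibril protein, Xist (4.41), Efemp1 (4.21), the matrix protein fibulin-3, Id1 (3.85), Gdpd3 (3.83), Pla1a (3.71), Ly6a (3.63), the surface antigen Sca-1, Mustn1 (3.58), Col2a1, whose FPKM + 1 was 11.3-fold higher, and Sap25 (3.45). The small nucleolar gene AF357399 was at 21.8 FPKM in this library and listed at 0 in the other 3. The lower genes were led by Ibsp and by the Y-linked Eif2s3y and Ddx3y (-4.88), with Eif2s3y listed at 0 in the library labelled KO. F13a1 (-4.74), which encodes the A subunit of coagulation factor XIII and is expressed by macrophages, was at 8.76 FPKM against 259.8 FPKM. It was followed by the ephrin receptor Epha3 (-4.45), the ectoenzyme Cd38 (-4.02), Wisp1 (-3.89), a matricellular Wnt target, Asb4 (-3.60), Itm2a (-3.59), the imprinted non-coding RNA H19 (-3.52) and the serotonin receptor Htr1b (-3.48). The entry Rps27,Rps27rt (-4.31) was uncertain, because Rps27rt alone was at 2077 and 633 FPKM in the opposite direction, and the sum of both entries was 2108 FPKM in the library labelled KO and 1267 FPKM in the library labelled WT.

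Of the gene lists, 18 of 25 stood apart under induction, beside 1.2 for lists of independently drawn genes, which is again no chance level. Of 19 osteoblast and bone matrix genes, 12 were lower in the induced library labelled KO, 2 were higher and 5 were within the rule. The median was -1.58, below all 10000 random lists. Dmp1, a matrix protein of osteocytes, had a ratio of -1.98, Omd -1.97, Spp1, which encodes osteopontin, -1.96, and Col1a2, a chain of type I collagen, -1.58. Macrophage markers were abundant in every library, and the cells that expressed Spp1 and the other list genes were not identified. Runx2, the master transcription factor of osteoblasts, was at 3.11 and 7.10 FPKM (-0.98), just short of the rule. The higher genes were Msx2 (1.32) and Bglap2 (1.16), which encodes osteocalcin. The fibrillar matrix list had a median of -0.83, below all random lists, with 7 of 22 genes lower, among them Postn (-2.21), Thbs1 (-1.96) and Fmod (-1.55), and with Dcn (2.05) higher. The marrow stromal list had a median of -0.79, below all random lists, yet its members went both ways, with 6 of 21 genes lower, 5 higher and 10 within the rule. Among surface markers of MSCs, Nt5e (-2.64) was lower, and Ly6a (3.63) and Thy1 (2.43) were higher. Grem1 (-2.58), a secreted BMP antagonist, was lower. With the mean in place of the median this list lay at the percentile 4.29. The BMP target list had a median of 0.90, above all random lists, with Id1 (3.85), Atoh8 (2.88) and Dlx2 (2.02) among 8 higher genes and Grem1 among 3 lower ones of 16. In the DLX and HOX list, with a median of -0.51 (percentile 0.545), Dlx6 (-1.89), Dlx5 (-1.42) and Hoxc6 (-1.20) were lower and Dlx2 was higher, and with the mean this list lay at 3.85. The Wnt target list, which also holds feedback genes, did not stand apart (median -0.02, percentile 56.1). Of its 15 genes, 5 were lower, including Wisp1, Sfrp2 (-3.30) and Lgr5 (-2.27), and 2 were higher, Sfrp1 (2.12) and Wif1 (2.04). The related genes Sfrp1 and Sfrp2 thus went opposite ways. With the mean in place of the median it stood apart at -0.47 (percentile 1.88). The libraries compared for these bone and stromal lists also differed in Xist (log2 ratio 4.41) and Ddx3y (-4.88).

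Of 20 adipocyte genes, 4 were higher in the induced library labelled KO and 1 was lower, with a median of 0.56 (percentile 99.96). The hormone gene Adipoq, at 4.93 FPKM in the library labelled KO and 1.17 FPKM in the library labelled WT, had a ratio of 1.45. The transcription factor Cebpb had 1.37, the fatty acid carrier Fabp4 1.28 and Pparg 1.15, and the fatty acid transporter Cd36 was at -1.23. Macrophage markers were abundant in every library, and the cells that expressed these genes were not identified. With the GC trend removed the percentile of the list was 95.6. All 32 measured cell cycle genes had ratios above 0, with a median of 1.16 that lay above all random lists, and 18 of them passed the rule. Rrm2 (2.09) and Mcm5 (1.83), both needed for DNA replication, and Birc5 (1.92) and Plk1 (1.71), both acting in mitosis, had the largest ratios. The cell cycle arrest and senescence list had a median of -0.45 (percentile 0.09). Its members went both ways, with the inhibitor Cdkn1c (-2.30) and Hmga2 (-1.72) lower and Lmnb1 (1.63) and Hmgb2 (1.17), which are more abundant in dividing cells, higher. Cdkn2a, whose products include the senescence marker p16, was at 203 FPKM in the library labelled KO and 132 FPKM in the library labelled WT. A gene-level value does not give the level of p16 alone. Cdkn1a, which encodes the inhibitor p21, was at 152 and 249 FPKM. The list of factors secreted by senescent cells had a median of 0.80, above all random lists, with 7 of 25 genes higher, including Ccl8 (2.76) and Ccl2 (2.06), and 3 lower, including the matrix proteases Mmp13 (-3.23) and Mmp10 (-2.47). Among its genes with at least 5 FPKM the percentile was 69.8. Cholesterol synthesis genes had a median of 0.99, above all random lists, with 8 of 19 higher, among them Fdps (1.51), Mvk (1.37) and Insig1 (1.28). In the glucocorticoid list (median -0.57, percentile 0.07), Pdk4 (-1.67), Angptl4 (-1.53) and Errfi1 (-1.45) were lower and the metallothionein gene Mt2 (2.92) was higher. These ratios come from the same libraries whose Y-linked genes differed.

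Markers of other cells differed as well. The macrophage list had a median of 0.57 (percentile 99.89), with 4 of 22 genes higher, namely Cd14 (2.46), Cd74 (2.39), H2-Aa, at 3.04 FPKM against 0.430 FPKM, and Fcer1g (1.02), while Lyz2 and Ptprc, the pan-leukocyte antigen, had ratios of -0.01 and -0.06. The contractile list (median 0.51, percentile 98.3) had Des (1.97), Cnn1 (1.59) and Actg2 (1.40) higher, and among its genes with at least 5 FPKM the percentile was 96.4. The chondrocyte list (median 0.80, percentile 99.82, 6 genes) had Col2a1 and Col10a1 (1.42) higher and Col11a1 (-2.91) lower, and it lay at 95.8 with the mean in place of the median and at 86.4 without a filter. The type I interferon list had a median of 0.46 (percentile 99.89) with 0 of 18 genes past the rule, led by Bst2 (0.98). The immediate early list had a median of 0.38 (percentile 98.6), with Ier3 (1.01) higher and Egr1 (-1.13) lower, and lay at 81.3 with the GC trend removed and at 84.4 with the mean. The ribosomal protein list had a median of 0.47 (percentile 97.9), with Rpl38 at 0.91 and Rps15 at 0.85. It was apart in 5 of 11 other settings. The trend across genes ran opposite to that in control medium, with a Spearman rho of -0.35 with transcript length and 0.40 with GC content over 11489 genes. The sex list, with 4 of 5 genes lower, had a median of -3.20. Lists within the random range were H3K9 methylation (median -0.24, with Uhrf1 at 1.71), osteoclast (-0.23), respiratory chain (0.32), glycolysis (0.16, with Adm at 1.62 and Bnip3 at -1.02), unfolded protein (-0.07) and NRF2 (0.09, with Gsta4 at 2.08, Mt1 at 1.95 and Gsta3 at -1.74). Fewer than 5 genes were measured of the other hematopoietic (median -0.13, with the platelet gene Pf4 at 2.44 and Mcpt8 at -1.23), endothelial (0.71, with Emcn at 1.18) and skeletal muscle (Acta1, 2.21) lists.

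**Figure D2:**
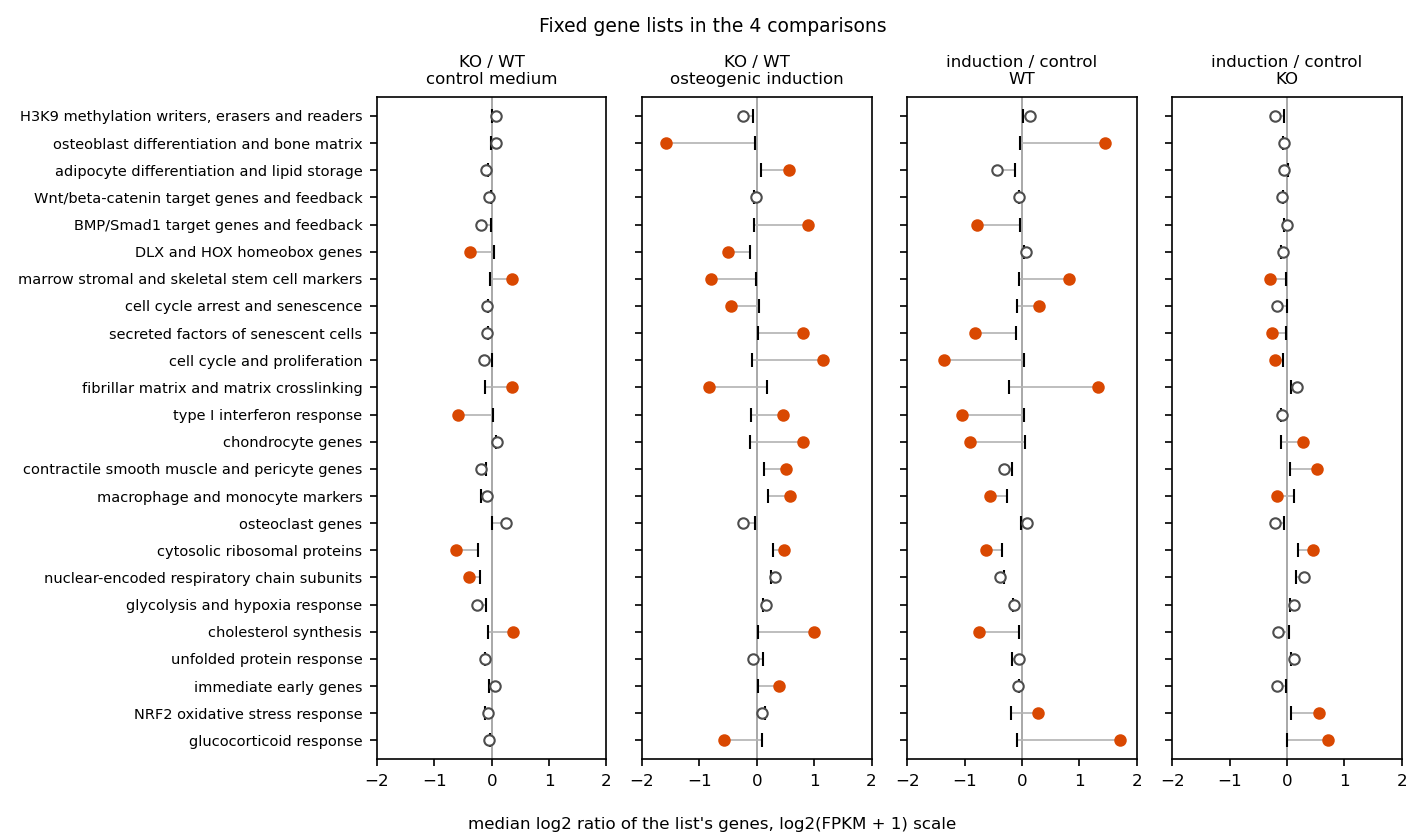
Median log2 ratio of each of 24 gene lists in the 4 comparisons, with filled points for lists that stood apart from random lists, open points for the others and a vertical tick at the median of the random lists. The osteoblast list was at -1.58 for KO against WT under induction and at 1.44 for induction against control in the libraries labelled WT, and close to 0 in the other comparisons. Both of these values rest on the same induced library labelled WT and are not separate results.

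Few genes were higher or lower in the libraries labelled KO in both media. Of 11487 genes measured in both comparisons, 20 were higher in both, where independent lists would share 4.5, and 12 were lower in both, where independent lists would share 5.6. The higher genes included Dcn, Pla1a, Col2a1, the globin Cygb (1.46 in control medium and 2.79 under induction), Col10a1 (1.39 and 1.42), a collagen of hypertrophic cartilage, Ndufa4l2 (1.35 and 2.21) and Rem1 (1.25 and 1.57). The lower genes that the naming rule admits were Pcolce2 (-1.32 and -1.63), an enhancer of collagen maturation, Il34 (-1.12 and -2.06), a ligand of the macrophage growth factor receptor, Crabp2 (-1.11 and -1.48), a retinoic acid carrier, and Podnl1 (-1.40 and -1.03). Opposite directions were more frequent, with 27 genes higher in control medium and lower under induction (3.9 for independent lists) and 52 the other way (6.5). Across genes the log2 ratios of both media ran against each other, with a Pearson r of -0.37 and a Spearman rho of -0.55, and genes are not independent replicates. The sum of genes in the same direction, 32, was 21 without small RNA genes and 19 without genes listed at 0.

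**Figure D3:**
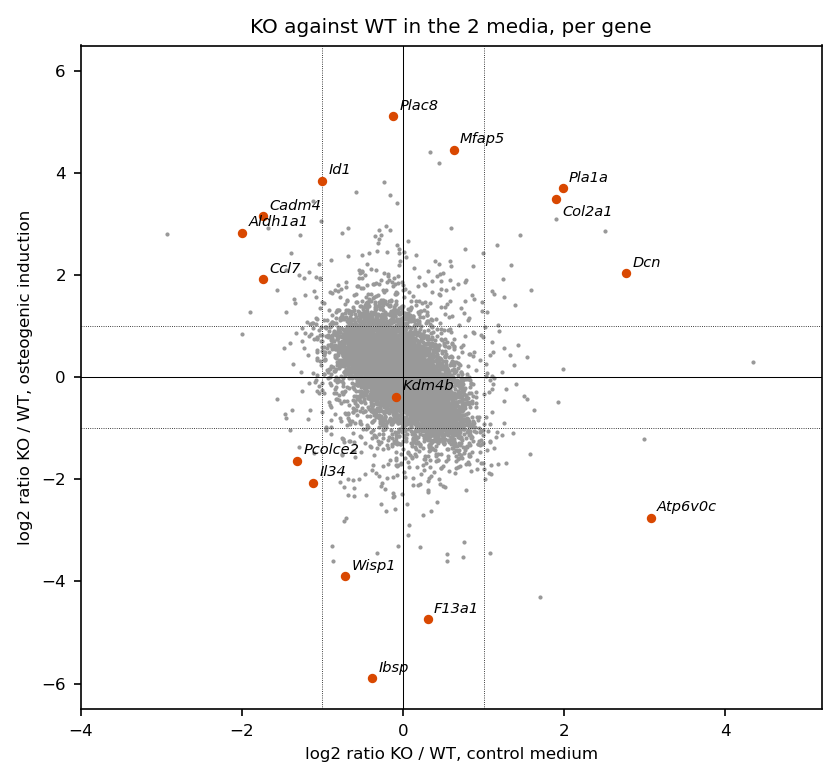
Log2 ratio of KO against WT for 11390 genes, small RNA genes and Rn45s left out, in control medium on the horizontal axis and under osteogenic induction on the vertical axis, with 1 point per gene and dotted lines at the size rule of 1. Dcn, Pla1a and Col2a1 were higher in both media, and across all 11487 genes the ratios of both media ran against each other (Spearman rho -0.55).

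The third comparison asked which genes differed with osteogenic induction in the cells labelled WT. It shared the induced library labelled WT with the second comparison, so opposite ratios in both are not separate results. It set libraries of separately deposited tables side by side, and how these tables were normalized to each other was not given in the sources used here. Of the osteoblast genes 12 of 19 and of the fibrillar matrix genes 14 of 22 were higher in the induced library, with Ibsp at 176.8 FPKM against 1.74 FPKM (log2 ratio 6.02), Postn, a matrix protein of bone surfaces and fibrous tissue, at 883 against 75.8 FPKM (3.53) and Lox, which crosslinks collagen, at 582 against 93.5 FPKM (2.63). Of the cell cycle genes, 25 of 33 were lower, with Rrm2 at 8.08 against 46.4 FPKM (-2.38), and so was Cd74, the chaperone of class II molecules, at 5.42 against 155 FPKM (-4.60). By the size rule, 1834 of 12094 genes differed, 873 higher and 961 lower. The libraries also differed in the sex-linked genes, with Ddx3y higher (4.87), Eif2s3y at 39.4 FPKM against a control library listed at 0, and Xist lower (-4.55).

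Of 19 osteoblast genes, 12 were higher and 2 lower in the induced library labelled WT, with a median of 1.44 that lay above all random lists. Enpp1 (2.15), Tnfrsf11b (2.02) and Ibsp were higher and Msx2 (-2.03) was lower. Of the fibrillar matrix genes, 14 of 22 were higher and 0 lower (median 1.32, above all random lists), with Thbs1 (2.33) and Col12a1 (2.32) among them. The glucocorticoid list had a median of 1.71, above all random lists, with 9 of 13 higher, including Fkbp5 (4.54), Tsc22d3 (2.43), Pdk4 (2.08) and Ddit4 (2.02). Its 1 lower gene was Mt2 (-1.23). The cell cycle list had 25 of 33 genes lower (median -1.35, below all random lists), including Birc5 (-2.41) and Cenpa (-2.28). Lower medians below all random lists were also found for the interferon (-1.04, with Ifit3 at -2.36), cholesterol synthesis (-0.74, with Fdps at -1.45) and senescent cell secretion (-0.82, with Ccl8 at -3.54) lists. The BMP target list (median -0.79, percentile 0.02) had 7 of 17 genes lower, including Id1 (-4.19), Atoh8 (-2.41) and Id2 (-2.08). Its 4 higher genes included Dlx6 (1.57), Dlx5 (1.44) and Grem1 (1.03). The marrow stromal list (0.82, above all random lists) had 10 of 21 genes higher, including Nt5e (2.79) and Vcam1 (2.44), and 5 lower, including Ly6a (-4.15). The macrophage list (-0.56, percentile 1.69) had 7 of 22 genes lower, including Cd14 (-3.14), and 1 higher, the mannose receptor Mrc1 (2.04). The adipocyte list did not stand apart (-0.43, percentile 2.55), with Plin4 (-1.48), Pparg (-1.43) and Adipoq (-1.40) lower, but stood apart in 6 other settings, at percentiles from 0.16 to 2.3. In all, 15 of 26 lists stood apart, among them also chondrocyte genes (-0.91), cell cycle arrest (0.29), ribosomal proteins (-0.63), NRF2 targets (0.28) and the sex list (3.20). The arrest list had 3 genes higher and 3 lower of 21, and the NRF2 list 4 higher and 4 lower of 21. Across 11642 genes the ratio had a Spearman rho of 0.36 with transcript length and -0.34 with GC content. Calls were lost for the macrophage list at a minimum of 5 FPKM (percentile 3.18) and with 20 expression bins (2.74), for the stromal (95.3), arrest (85.7) and chondrocyte (30.0) lists with the mean, for the chondrocyte list without a filter (8.58), for the arrest list with the GC trend removed (95.7), and for the arrest (95.2), ribosomal (3.16) and NRF2 (97.0) lists with the length trend removed. With the length trend removed, the other hematopoietic list (median -0.67, percentile 5.47) stood apart at 2.4. The genes with the largest ratios further included F13a1 (7.30), Cxcl14 (-4.41) and Cadm4 (-4.19), and Rn45s and Erdr1 (4.96) with the uncertainty described above.

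The fourth comparison asked the same of the cells labelled KO, again across separately deposited tables. Of the glucocorticoid list, 4 of 13 genes were higher in the induced library, including Fkbp5 at 79.3 against 3.94 FPKM (log2 ratio 4.02), Tsc22d3, the leucine zipper protein GILZ, at 126 against 28.0 FPKM (2.13) and Mt2 at 791 against 152 FPKM (2.37). Of the osteoblast genes, 17 of 19 were within the size rule, 8 with ratios above 0 and 11 below 0 over all 19. Ibsp was at 1.98 against 1.11 FPKM (0.50), Col1a1, the main collagen of bone, at 477 against 330 FPKM (0.53), Spp1 at 1658 against 3210 FPKM (-0.95) and Alpl at 4.58 against 8.33 FPKM (-0.74). Cd74 was lower, at 32.6 against 96.0 FPKM (-1.53), and so was the class II gene H2-Aa, at 3.04 against 19.4 FPKM (-2.34). By the size rule, 307 of 11748 genes differed, 181 higher and 126 lower, and 203 without small RNA genes. Both libraries had the same pattern of sex-linked genes.

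Of 19 osteoblast genes in the libraries labelled KO, 1 was higher, Smpd3 (1.18), and 1 lower, Sp7 (-1.02), and the median was -0.06 (percentile 53.5). The glucocorticoid list had a median of 0.72, above all random lists, with 0 genes lower, and the NRF2 list, genes of the oxidative stress response, 3 of 21 higher and 0 lower (0.57, above all random lists), with Gsta3 (1.58) and Gsr (1.14). The contractile list had a median of 0.52 (percentile 99.97) with 0 of 13 genes past the rule. The ribosomal list had a median of 0.45 (percentile 99.99), all 36 genes being above 0, beside a rho of -0.35 with transcript length and 0.46 with GC content across genes. Lists that lay low were senescent cell secretion (-0.27, percentile 0.12), with Igfbp5 (-2.13), Mmp12 (-1.83) and Cxcl5 (-1.69) lower, macrophage (-0.17, percentile 0.14), marrow stromal (-0.29, percentile 0.27), with Grem1 at -1.46, cell cycle (-0.22, percentile 1.29) with 0 of 34 genes past the rule, and endothelial (-0.75, percentile 0.05), where 0 of 5 genes were lower by the rule and Emcn (1.06) was higher. In all, 10 of 26 lists stood apart, the remaining one being the chondrocyte list (0.27, percentile 98.5). The cell cycle call was lost in 4 of 11 other settings (percentiles 3.44 to 26.3), the stromal call in 3 of 11 (3.17 to 24.2), the endothelial call without a filter (17.5) and with the mean (12.8), the senescent cell secretion call with the GC trend removed (27.4), and the chondrocyte call with a pseudocount of 5 (97.0) and with the mean (80.0). Calls were gained by the osteoclast list (median -0.21) in 3 settings (0.7 to 2.38), the arrest list (-0.17) with either trend removed (0.79 and 1.66), the Wnt (-0.09, to 0.39) and immediate early (-0.18, to 0.11) lists with the GC trend removed, and the fibrillar matrix list (0.17, to 99.8) with the length trend removed. Other genes with large ratios were Dpep1 (2.49), the vasodilator peptide gene Adm (2.34), Gfra4 (2.34) and the clock gene Nr1d2 (-1.99). Of 11548 genes measured in both induction comparisons, 49 were higher in both (9.1 for independent lists) and 41 lower in both (8.1). A further 19 were higher in the libraries labelled WT and lower in those labelled KO (6.6), and 30 the other way (11.2). Across these genes, which are not independent replicates, the ratios of both induction comparisons had a Pearson r of -0.08 and a Spearman rho of -0.31. The difference between the induction responses was not tested, since each rests on single libraries.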

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

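The tests of the macrophage share, of exchanged libraries, of the sex of the animal and of the Kdm4b level were chosen only after the result was seen, and the choice to remove the length and GC trends and the use of the control library labelled WT as the reference were also added after the data had been seen. All results here are differences of direction between single libraries, and none of these differences was tested.

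In the induced library labelled KO, 12 of 19 osteoblast, 7 of 22 fibrillar matrix and 6 of 21 stromal genes were lower than in the induced library labelled WT, and the medians of the fibrillar matrix list (-0.83, against 0.35 in control medium) and of the stromal list (-0.79, against 0.36, a call lost with the mean, at the percentile 4.29) were opposite to those in control medium. More macrophages and fewer stromal cells in the induced KO culture would lower the stromal markers together. Of these markers 5 were higher by the size rule and 6 were lower, so they did not fall together. The counts were known when this test was set, and the cells that expressed the markers were not identified. The test therefore decides nothing on this cause. Libraries exchanged between control and induction would leave one induced library without the glucocorticoid response, but the lowest induced level of Fkbp5 was 19.3 times the highest control level. The sex or another property of the animal behind the induced WT library may contribute and cannot be told apart from genotype, since the number of libraries with Ddx3y of at least 1 FPKM was 1. An effect of the loss of Kdm4b on the response to induction was not excluded. The Kdm4b level showed no such loss by the size rule (log2 ratios -0.08 and -0.38). With the control library labelled WT as the reference, which differs in medium as well, 334 genes differed from the induced library labelled KO, against 1273.

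Across genes the ratios of KO to WT ran opposite in the 2 media, and the ribosomal protein list followed, with medians of -0.62 in control medium and 0.47 under induction, and of -0.63 with induction in the libraries labelled WT and 0.45 in those labelled KO. These medians come from comparisons that share libraries and are not independent of each other. With the trend with transcript length removed, the rho of -0.55 was -0.46 over 11065 genes, and it was -0.46 with the trend with GC content removed, so neither trend alone accounts for the whole relation. With both removed together it was -0.37, which leaves open how much such a technical trend contributes. The ribosomal list in control medium stayed at the percentile 0 with the trend with transcript length removed (median -0.41). It also stayed at the percentile 0 with the trend with GC content removed (median -0.56), which argues against either as the whole cause. Under induction it lay at 91.0 (median 0.22) and 75.0 (median 0.28), where either trend may contribute. That call, at the percentile 97.9, was also lost in settings that removed no trend. These were a minimum of 5 FPKM (96.8), genes listed at 0 left out (97.3), 20 expression bins (92.8) and the mean (96.7). Its loss with a trend removed therefore does not tie the call to that trend. The trends placed the control WT and induced KO libraries on one side and the control KO and induced WT libraries on the other. Some entries that share sequence with other genes split the same way. Atp6v0c was at 64.9 and 99.99 FPKM in the former libraries and at 555 and 678 FPKM in the latter. Rps27rt was at 2256 and 2077 FPKM against 761 and 633 FPKM. Erdr1 and Rn45s were low in the control WT library alone. Such a split may be technical, which was not tested. A difference between batches of libraries and an effect of genotype that depends on the medium cannot be told apart by the trends.

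Kdm4b was at a similar level in libraries labelled KO and WT. Exchange of the labels within a medium cannot be told from correct labels, since the log2 ratio of Kdm4b in control medium was -0.08. Deletion of part of the gene, or of the gene in part of the cells, which a gene-level FPKM does not resolve, could leave a ratio such as the -0.38 seen under induction, and this test decides nothing either. Read coverage along the gene was not analysed here.

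Other lists and genes also had opposite directions between the media or between the genotype labels. The interferon list had a median of 0.46 under induction against -0.58 in control medium for KO against WT, a difference that was not tested. The stromal list had a median of -0.29 for induction against control in the libraries labelled KO against 0.82 in those labelled WT, calls that were lost in 3 of 11 and 1 of 11 other settings, and the difference was not tested. The chondrocyte list of 6 genes had a median of 0.27 against -0.91 in the same comparison, but means of 0.05 and -0.15 that did not stand apart (percentiles 80.0 and 30.0), and the difference was not tested.

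Among single genes, for KO against WT, the direction under induction was opposite to that in control medium, with no test of the difference, for Atp6v0c (-2.75 against 3.08) and the entry Amd1,Amd2 (-1.21 against 2.99), both of which share sequence with other genes. It was opposite the other way, likewise untested, for Aldh1a1 (2.83 against -1.99), Ugt1a6b (1.29 against -1.90), Cadm4 (3.16 against -1.73), Ccl7 (1.93 against -1.73), Pmp2 (2.93 against -1.68), Cryab (2.09 against -1.45), Id1 (3.85 under induction, and 56.5 FPKM against 114 FPKM in control medium) and Sap25 (3.45 against -1.11). The entries Rps27,Rps27rt (-4.31 against 1.70) and Rps27rt (1.71 against -1.57) had opposite ratios to each other in each medium and are not separate findings, since they share sequence and their sum was 2490, 1523, 1267 and 2108 FPKM in the control WT, control KO, induced WT and induced KO libraries.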

How the results depend on the processing

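The settings that left out small RNA genes or genes listed at 0, that removed a trend, or that changed the reference library were chosen only after the data had been seen. The labels carry no replicate numbers that would pair libraries, and no result comes from a test. No list that stood apart and no named gene past the size rule reversed its direction. Reversal was not checked for other lists and genes, nor with the control library labelled WT as the reference, where only the genes past the rule were counted. Under other settings, 32 counts of genes were within 1.5 times the main count and 16 were not, and the count of list calls was within it in all 11. For KO against WT in control medium the 284 genes became 559 with a pseudocount of 0.1, 149 with a pseudocount of 5, 176 without small RNA genes and 126 with a size rule of 1.5. Under induction the 1273 genes became 1931 with a pseudocount of 0.1, 535 with 5 and 461 with a size rule of 1.5. With the control library labelled WT as the reference 334 genes differed. That pair differs in medium as well as in genotype label, so it is another comparison and not another setting of the same one. For induction against control, the 1834 genes of the libraries labelled WT became 801 with a pseudocount of 5. The 307 of those labelled KO became 535 with 0.1, 168 with 5 and 203 without small RNA genes. The 32 genes in the same direction in both media became 67 with 0.1, 17 with 5, 21 without small RNA genes and 19 without genes listed at 0. A larger pseudocount or size rule counts fewer genes by its construction, and for the reference library the cause was not tested. Lists kept their status, apart or within the random range, in 1060 cases, lost a call in 39 and gained one in 19. Named genes kept their side of the size rule in 3004 cases, lost it in 135 and gained it in 17. The 25 list calls of the main comparisons numbered 19 to 26 under the other settings. Median-ratio scaling left the status of all 103 list percentiles, apart or within the random range, unchanged. Entries sharing a symbol and entries without an OK status gave no alternative values, since no symbol was repeated and no status was given. The depth is unknown, so no limit of detection can be given for genes listed at 0.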

Other observations

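The 4 lists described here, of MHC class II genes, glucocorticoid-regulated macrophage genes, fibroblast progenitor genes and imprinted growth genes, were composed after values had been seen, the lists without members already named were computed after the full lists, and the test of the imprinted list was written before its own result was known. The list of genes that present antigen on MHC class II had 4 of 8 genes lower and 0 higher with induction under each genotype label, with medians of -0.93 (percentile 0.01) in the libraries labelled WT and -0.88 (below all random lists) in those labelled KO. These medians rest on Cd74, H2-Aa and H2-Ab1, which the naming rule had already taken, and without them the list did not stand apart (-0.26, percentile 17.3, and -0.11, percentile 37.3). H2-Eb1, a chain of a class II molecule, had log2 ratios of -2.50 and -1.52, and the co-stimulatory gene Cd86 of -0.77 and -0.67. The list of genes that macrophages express under glucocorticoids lay high with induction under both labels, with medians of 1.90 (9 of 11 genes higher) and 0.88 (4 of 11 higher), both above all random lists, and 0 genes lower. Without F13a1, Mrc1 and Thbs1, already named, the medians were 1.68 and 0.88, still above all random lists. Ms4a6b had ratios of 4.00 and 1.92, Pla2g7, a secreted phospholipase, of 4.22 and 1.99, and the scavenger receptor gene Stab1 of 1.48 and 1.04. For KO against WT, the MHC class II list had a median of -0.34 (percentile 1.41, and 10.9 without the named members) in control medium and 0.21 (percentile 87.7) under induction, and the list of glucocorticoid-regulated macrophage genes 0.32 (percentile 99.6) and -0.95 (below all random lists), or 0.34 (percentile 98.8) and -0.59 (percentile 0.17, 3 of 8 genes lower) without the named members. Cd74, H2-Aa and H2-Ab1 belong to the fixed macrophage list as well, as does Mrc1 of the glucocorticoid-regulated list, and the difference between the labels was not tested.

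Most genes of fibroblast progenitors, which mark connective tissue cells with little bone gene expression, were lower in the induced than in the control library labelled WT. Of 11 measured genes, 9 had ratios below 0, and 2, Dcn (0.21) and Pcolce2 (0.42), had ratios above 0. For KO against WT under induction the list had a median of 2.28, above all random lists, with 8 of 11 genes higher and 1 lower. Cd34 was at 7.68 FPKM in the library labelled KO and 0.262 FPKM in the library labelled WT (log2 ratio 2.78), and the log2 ratios of Ly6c1 and Cd248 were 2.82 and 2.28. In control medium the median was -0.19 (percentile 14.5). With induction it was -1.55 (below all random lists, 6 genes lower) in the libraries labelled WT and 0.06 (percentile 67.9) in those labelled KO. Ly6a, Mfap5, Efemp1, Dcn and Pcolce2 had been named for their ratios before this list was composed, and without them the median for KO against WT under induction was 1.67, still above all random lists, with 4 of 6 genes higher. The libraries compared differed in their sex-linked genes as well.

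H19 was high in the induced WT library alone, at 30.7 FPKM against 0.381, 1.32 and 1.76 FPKM in the control WT, control KO and induced KO libraries. The hypothesis of a wider rise of imprinted growth genes in the induced WT library was tested on 12 imprinted growth genes with H19 left out. For KO against WT under induction their median was -0.92, at the percentile 0, as the hypothesis needs, though H19 and other genes had already been seen to differ in this library. Without Cdkn1c, which the naming rule had also taken, the median of the 11 remaining genes was -0.81 (percentile 0.04), with 5 genes lower and 2 higher. With H19 the list had a median of -1.04 with 7 of 13 genes lower and 2 higher, Grb10 (-1.95) and Igf2 (-1.75) being lower and Meg3 (2.04) and Rian (1.26) higher. The median was -0.12 (percentile 22.1) in control medium, 0.98 (above all random lists) with induction in the libraries labelled WT and 0.07 (percentile 85.4) in those labelled KO. A property of that culture or animal cannot be told apart from an effect of genotype, with 1 library in each group.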
